A study of Mus musculus with 586 samples.

How the data were processed

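The series holds Geo-seq libraries of C57BL/6 mouse embryos at E5.5, E6.0, E6.5, E7.0 and E7.5. Per the labels, embryos were embedded in OCT and cryosectioned, cells were taken from the sections by laser microdissection, RNA was extracted with guanidine isothiocyanate, and libraries were made with Nextera XT. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.8b and the deposited values are FPKM from Cufflinks 2.1.1, in 1 table per embryo. The gene annotation and the options of these tools were not given in the sources used here.

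Columns were matched to samples by embryo, section number and region code. Of 586 samples, 113 had no column of that name, and 111 columns could not be mapped to a sample; both were left out. Most lie at E7.5, where the labels of embryos 1 and 2 code regions B, C and D and those of embryos 4, 5 and 6 code C and D, while the columns of these embryos use P, L and R codes. So no P column of E7.5 embryos 1 and 2 and no L or R column of these 5 embryos was used, and at E7.5 P minus A rests on 4 embryos and R minus L on 1. The codes A, P, L, R, M, MA, MP, EA, EP and VE were read as in the published atlas of these embryos, since the labels do not spell them out; E1, E2, M1 and M2 were not compared. The 18 tables list 23361 genes, of which 760 were at 0 in every library, with no mitochondrially encoded genes and no spike-ins. Read counts were not used here, and with FPKM alone no count-based tool was run. Rough depth came from the FPKM worth of 1 read in genes with 1 annotated transcript, and was 1.82 to 8.71 M reads (1 M = 1000000) for the embryos' median libraries; relative depth within an embryo ranged from 0.241 to 3.23 times its median. FPKM sums ran from 53064 to 1806706. No 2 libraries were identical, and 4 were led by a single small RNA gene with over 50% of the sum. Transcript-level analysis, alternative splicing and allele-specific expression were not analysed here.

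The embryo was the replicate. In each embryo and section that held a library of every region of a contrast, the difference of log2(FPKM + 1) between the regions was taken and averaged over sections, so that every contrast was paired within the embryo. As a check of the pairing, the deviations of A and of P from their stage means, over 9541 and 9684 genes, correlated within the same embryo by 0.660 to 0.889 at E6.5 and by 0.461 to 0.759 at E7.5, against at most 0.549 and 0.0349 between embryos. These are correlations across genes, which are not independent.

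Differences were fitted by stage in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation (trend and robust), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All stages of a contrast shared 1 spread per gene. A gene was tested where its mean was at least 1 FPKM in the libraries of at least 1 stage. P was compared with A at each stage and in its change from E6.5 to E7.5, endoderm (EA and EP) with A and P in 6 embryos and in its change, mesoderm with P and with endoderm in 4, EP with EA in 6, MP with MA in 2 and R with L in 3; the means weighted the stages equally. Gradients at E6.5 were slopes per embryo on the section number, scaled from 0 at the most distal to 1 at the most proximal section with a library of that region. Levels of A and P were compared between stages on libraries rescaled to a sum of 1000000. SE is the moderated standard error.

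Gene lists written before the data were examined cover 30 groups of markers, pathways and signs of other tissues, namely the 29 named in the account of E6.5 and mitochondrially encoded genes. Their members tested in a contrast were counted by call, also adjusted over the list alone. Each list was tested with camera at a preset correlation between genes of 0.01 and at an estimated correlation. With an estimated correlation camera takes its degrees of freedom from the fit. These were 1 to 3 in both endoderm and both mesoderm contrasts, EP minus EA, MP minus MA and R minus L. There a list that did not pass may lack degrees of freedom, whatever the correlation of its genes. The genes named are the up to 10 higher and 10 lower with the largest difference among those past the threshold, with a log2 difference of at least 1, the same sign in every embryo and a mean of at least 5 FPKM, without predicted genes known by a clone or model number; up to 4 members of each list with the smallest p; and T, Mixl1, Eomes, Mesp1, Sox2, Otx2, Pou5f1, Nanog, Pou3f1, Foxa2, Sox17 and Ttr. Coordinates are those of GENCODE vM21 on GRCm38. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

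The procedure was tested on simulated values per embryo at the fitted spread of each contrast, with 100 genes planted at each size. Of genes planted at a log2 difference of 1 and 2, P minus A at E6.5 found 92 and 100%, at E7.0 39 and 96% and at E7.5 84 and 100%; endoderm minus epiblast found 99 and 100%, its change 21 and 96%, and the slope in P 33 and 98%. Each was rerun with other pseudocounts, filters, scalings, sections and spreads, without the block on the embryo, with only the stages of the contrast and without each embryo in turn.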

Results

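Geo-seq measures RNA from small groups of cells that are captured by laser from known positions in cryosections of an embryo. The series profiles C57BL/6 mouse embryos from before to after gastrulation, at embryonic days E5.5, E6.0, E6.5, E7.0 and E7.5. Of 586 samples, 473 could be matched to a column of values, and these came from 18 embryos: 22 libraries at E5.5 and 22 at E6.0 from 2 embryos each, 109 at E6.5 from 6 embryos, 101 at E7.0 from 2 embryos and 219 at E7.5 from 6 embryos. Each library carries a section number, with section 1 at the distal tip, and a region code. Following the published atlas of these embryos, A and P are read here as the anterior and posterior sides of the epiblast, L and R as its left and right sides, EA and EP as anterior and posterior endoderm, M, MA and MP as mesoderm with its anterior and posterior parts, and VE as visceral endoderm. The embryo was the replicate throughout, and regions of the same embryo were compared section by section.

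The values are FPKM of 23361 genes. A library had between 2683 and 11319 genes at 1 FPKM or more, with a median of 8949. From the FPKM worth of 1 read, the embryos' median libraries were put at 1.82 to 8.71 M reads (1 M = 1000000). Embryos 1 to 4 of E6.5 and 1 to 3 of E7.5 lay at the upper end of that range. Differences are given as differences of log2(FPKM + 1) with their standard error (SE), levels as mean FPKM ± SD over embryos, and adjusted p-values come from limma with Benjamini-Hochberg adjustment. The scale understates the fold of genes with low values.

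At E6.5, when the primitive streak forms, genes of the streak were higher in P than in A. Mixl1, a homeobox gene of the streak, was higher by 3.36 ± 0.24 on the log2 scale (SE, n = 6, adjusted p = 6.96e-07, higher in 6 of 6 embryos), at 80.5 ± 25.3 FPKM in P against 3.61 ± 2.53 in A. T, which encodes the T-box factor brachyury, was higher by 2.43 ± 0.30 (adjusted p = 4.15e-04), and Eomes, a T-box factor needed for mesoderm and definitive endoderm, by 1.98 ± 0.26. Fgf8, whose product cells need to leave the streak, reached 114 ± 42.2 FPKM in P against 24.8 ± 15.9 in A. Pou3f1, a POU-domain factor of neural ectoderm, was lower in P, at 17.5 ± 10.0 against 31.5 ± 13.5 FPKM, a difference of -1.10 ± 0.20 (adjusted p = 0.0134, lower in 6 of 6 embryos).

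Of 11351 genes tested at E6.5, 84 differed, 68 higher and 16 lower in P, and of 29 gene lists camera passed 11 at its preset correlation and 4 with an estimated one. Of 30 primitive streak genes, 16 were higher and 0 lower (21 and 0 adjusted over the list alone), with camera adjusted p = 1.64e-45, and adjusted p = 0.00159 with an estimated correlation. Apart from the genes above, its higher members included Fst, which encodes the activin antagonist follistatin (2.31 ± 0.28), Mesp1, a factor of nascent mesoderm (2.15 ± 0.49, adjusted p = 0.0496), Gsc (1.95 ± 0.28) and Frzb, a secreted WNT antagonist (1.58 ± 0.24). Snai1, which represses E-cadherin, rose by 1.78 ± 0.39 with the same sign in 5 of 6 embryos. Among 25 WNT pathway genes, 9 were higher and 1 lower (13 and 1 adjusted over the list alone, adjusted p = 0.00159 with an estimated correlation), among them the WNT target Sp5 (1.62 ± 0.19) and the ligand Wnt8a (1.51 ± 0.21). Of 17 NODAL pathway genes, 5 were higher and 0 lower (9 and 1 adjusted over the list alone). Among 10 left-right genes, 2 were higher and 0 lower (5 and 0). Both had adjusted p = 0.00279 with an estimated correlation. Lists share members, as these do, and are not separate signals. Of 13 anterior visceral endoderm genes, 4 were higher and 1 lower (6 and 2 adjusted over the list alone), with a median of -0.16 against an upward direction in camera and adjusted p = 0.272 with an estimated correlation; the members that rose, such as Lhx1 (1.43 ± 0.23) and Foxa2 (1.44 ± 0.28), also act in the streak and its derivatives.

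The lower genes included further epiblast genes. Utf1, a chromatin factor of undifferentiated cells, had 138 ± 76.0 FPKM in P and 229 ± 70.5 in A, and the amino acid transporter Slc7a3 50.4 ± 20.7 and 92.3 ± 15.4. Among 11 anterior epiblast and neural ectoderm genes, 0 were higher and 3 lower (0 and 6 adjusted over the list alone, adjusted p = 0.0902 with an estimated correlation). Of 20 epithelial genes, 0 were higher and 1 lower (0 and 6 adjusted over the list alone, adjusted p = 0.0797 with an estimated correlation), with the polarity gene Crb3 lower (-1.15 ± 0.25). Among 18 glycolysis genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), the glucose transporter Slc2a1 (-0.69 ± 0.15). Of 21 core and primed pluripotency genes, 1 was higher and 2 lower (3 and 4 adjusted over the list alone): Pou5f1 differed by -0.07 ± 0.16 (adjusted p = 1), Sox2 by -0.94 ± 0.27 (adjusted p = 0.191) and Nanog by 0.56 ± 0.19 (adjusted p = 0.456), and Otx2, a factor of the anterior epiblast, by -0.40 ± 0.16 (adjusted p = 0.714). None of these 4 passed the test.

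Of the remaining lists at E6.5, those of nascent and paraxial mesoderm, FGF pathway, node and axial mesoderm and mesenchymal genes passed camera at its preset correlation and not with an estimated one. Among 19 nascent and paraxial mesoderm genes, 2 were higher and 0 lower (5 and 0 adjusted over the list alone, adjusted p = 0.0749 with an estimated correlation). Of 19 FGF pathway genes, 3 were higher and 0 lower (3 and 1 adjusted over the list alone, adjusted p = 0.165 with an estimated correlation). Among 17 node and axial mesoderm genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation). Of 20 mesenchymal genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation). Among 15 definitive endoderm genes, 3 were higher and 0 lower (4 and 2 adjusted over the list alone) with a median of -0.16. Of 12 parietal endoderm genes, 2 were higher and 0 lower (2 and 0 adjusted over the list alone). Among 35 visceral endoderm genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone). Of 12 retinoic acid genes, 1 was higher and 0 lower (2 and 0 adjusted over the list alone). Among 13 extra-embryonic ectoderm and trophoblast genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone). By limma, 0 members passed among the cardiac and lateral mesoderm (12 tested), blood and endothelium (9), naive pluripotency (7), BMP (18), Hippo-YAP (13), Hox and Cdx (11), primordial germ cell (9), maternal decidua and blood (10), immediate early (13), cell cycle (22) and cilia (10) lists. Adjusted over the list alone, 1 member each way passed in the naive pluripotency list, 1 lower in the BMP list, 2 higher and 1 lower in the germ cell list, and 0 in the others. The mitochondrially encoded list had 0 members tested. Over all genes, 580 had an unadjusted p under 0.05.

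The count at E6.5 depended on single embryos. Without embryo 2, 3, 4, 5 or 6 it was 35, 37, 52, 46 or 34, and the values of embryo 6 stand in a table named for E6.0 although its labels give E6.5. Without E6.5 embryos 1 to 4 and E7.5 embryo 3 the count was 2, without embryos 5 and 6 it was 15, and a fit of the E6.5 embryos alone gave 290. Libraries rescaled to an equal sum gave 41 higher and 6 lower, and equal medians 46 and 24. In GRCm38 coordinates, T lies on chromosome 17, 8434423 to 8442496, Mixl1 on chromosome 1, 180693043 to 180697034, and Pou3f1 on chromosome 4, 124656807 to 124660655.

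**Figure D1:**
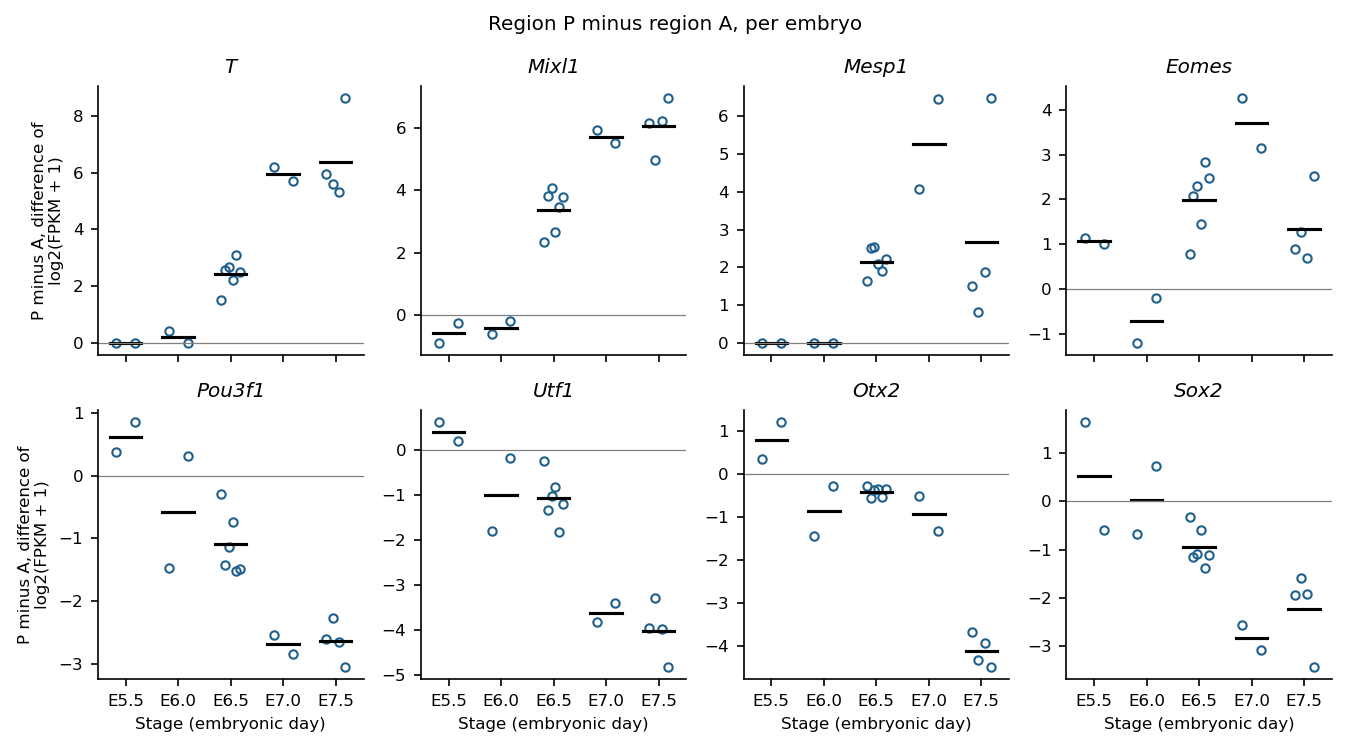
Difference between region P and region A in log2(FPKM + 1) for 8 genes at each stage, with 1 open circle per embryo and a black line at the mean. At E6.5 the mean difference was 3.36 for Mixl1 and -1.10 for Pou3f1, and at E7.5 it was 6.07 and -2.64.

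Along the proximal to distal axis of the P side at E6.5, a slope was taken in each embryo from the most distal section to the most proximal. Mesp1 rose toward the proximal end by 7.58 ± 0.40 over the full axis (SE, n = 6, adjusted p = 2.35e-10), from 0.0488 ± 0.079 FPKM in the most distal section to 135 ± 61.6 in the most proximal. Mixl1 rose by 6.86 ± 0.35, T by 6.54 ± 0.37 and Snai1 by 4.82 ± 0.35, each in 6 of 6 embryos. Id1, a direct target of BMP signals, rose by 7.23 ± 0.57, from 0.233 ± 0.444 to 162 ± 78.3 FPKM. Pou3f1 fell by 2.09 ± 0.40 (adjusted p = 0.00548), and Foxd3 and Sox3, transcription factors of the epiblast, fell by 1.81 ± 0.28 and 1.45 ± 0.30.

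Of 11628 genes, 178 had a slope in P, 164 upward and 14 downward toward the proximal end, and camera passed 13 lists at its preset correlation and 1 with an estimated one. Of 30 primitive streak genes, 21 rose and 0 fell (22 and 1 adjusted over the list alone, adjusted p = 0.00525 with an estimated correlation), among them Fst (4.57 ± 0.46), Evx1 (4.31 ± 0.28), Wnt3 (3.38 ± 0.35) and Eomes (3.31 ± 0.53). Among 26 WNT pathway genes, 13 rose and 0 fell (17 and 0 adjusted over the list alone, adjusted p = 0.0563 with an estimated correlation), with Sp5 (4.33 ± 0.34) and Frzb (3.75 ± 0.36). Of 17 NODAL pathway genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation), with the co-receptors Cfc1 (3.84 ± 0.71) and Tdgf1 (2.15 ± 0.50) and the antagonist Lefty2 (2.15 ± 0.51). Among 17 BMP pathway genes, 5 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), with Id2 (3.52 ± 0.45) and Msx2 (2.75 ± 0.52). Pou5f1, Nanog, Otx2 and Sox2 had slopes of 0.48 ± 0.46, 1.05 ± 0.40, -0.12 ± 0.51 and -0.75 ± 0.32, and none of them passed. The median of all genes was 0.36, and libraries rescaled to an equal sum gave 75 upward and 16 downward slopes with a median of 0.09, equal medians 88 and 45 with a median of -0.02. Without embryo 2, 3, 4 or 6 the count was 105, 107, 106 or 109, without embryos 5 and 6 it was 93, and without E6.5 embryos 1 to 4 and E7.5 embryo 3 it was 6. A fit of the E6.5 embryos alone gave 1695.

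On the A side, 5 of 11622 genes had a slope, all upward. They were Id1 (7.23 ± 0.44, adjusted p = 2.45e-07), Id2 (4.77 ± 0.48), Fst (2.74 ± 0.33), Wnt3 (2.57 ± 0.35) and Cxcl12, a chemokine (2.06 ± 0.31), each upward in 6 of 6 embryos. Id1 went from 0.408 ± 0.699 FPKM in the most distal section to 178 ± 75.8 in the most proximal. The streak genes Mixl1, Eomes, T and Mesp1 had slopes of 2.43 ± 0.62, 2.35 ± 0.53, 1.91 ± 0.54 and 1.79 ± 0.43, and did not pass. Of 28 primitive streak genes, 2 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.0652 with an estimated correlation). Among 12 BMP pathway genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation). Without embryo 1 or 6 the count was 8 or 3, and without E6.5 embryos 1 to 4 and E7.5 embryo 3 it was 0. Id1 lies on chromosome 2, 152736251 to 152737410, and Mesp1 on chromosome 7, 79792241 to 79793788.

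**Figure D2:**
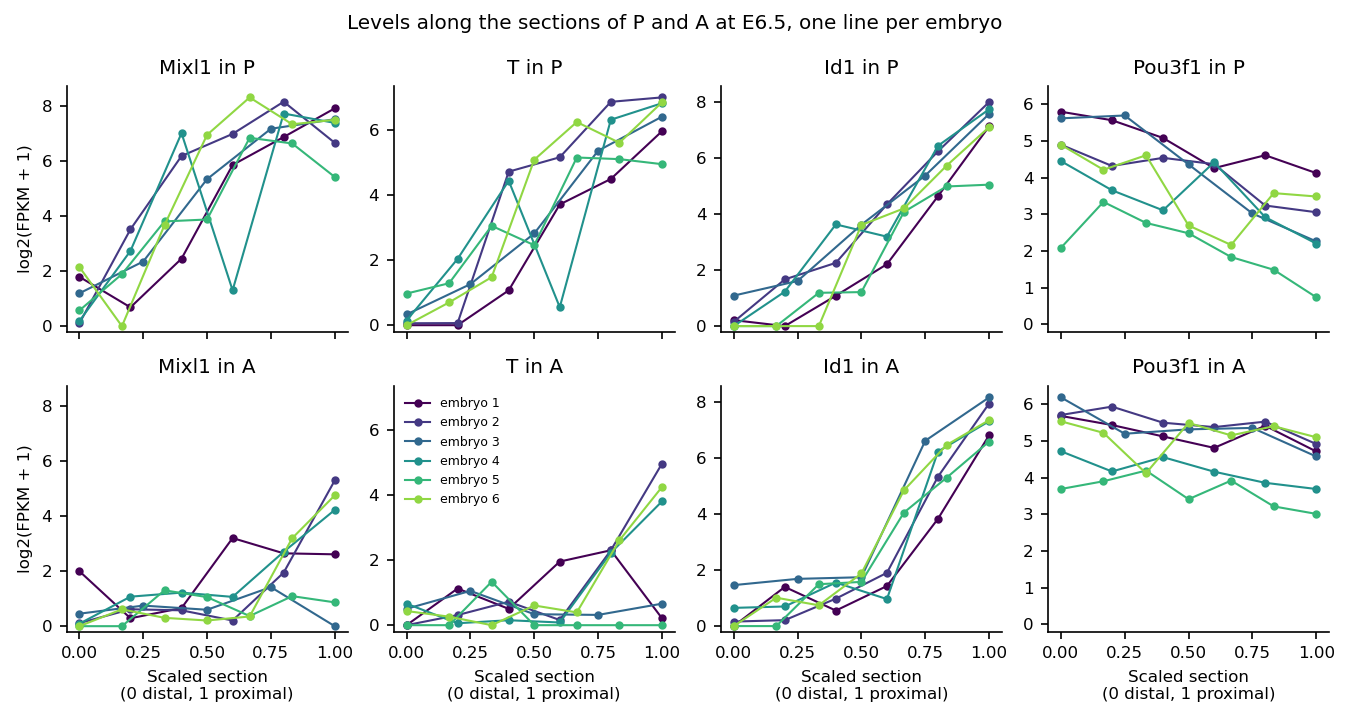
log2(FPKM + 1) of Mixl1, T, Id1 and Pou3f1 against section position, scaled from 0 at section 2 to 1 at the most proximal section, in P (top) and A (bottom), with 1 line per E6.5 embryo. Over that axis Id1 rose by 7.23 in P and 7.23 in A, while Pou3f1 fell by 2.09 in P.

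Before gastrulation the same contrast was made in 2 embryos per stage. At E5.5, T and Mesp1 were listed at 0 in P and A of both embryos, and Mixl1 differed by -0.56 ± 0.41 (adjusted p = 0.392), at 0.691 ± 0.879 FPKM in P and 5.15 ± 3.99 in A. Pttg1, which encodes the anaphase regulator securin, was higher in P by 3.25 ± 0.21 (SE, n = 2, adjusted p = 1.83e-07, both embryos), and Sdha, a subunit of succinate dehydrogenase, by 2.61 ± 0.34. Lman1, a cargo receptor of the secretory pathway, fell by 1.90 ± 0.21 toward P, and the repair endonuclease Apex2 by 2.31 ± 0.24. Pou5f1 was higher in P, at 139.6 ± 33.3 against 78.1 ± 5.35 FPKM (1.14 ± 0.29).

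At E5.5, 2 of 30 streak genes were higher and 0 lower (2 and 0 adjusted over the list alone). Of 21 core and primed pluripotency genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone). Among 19 FGF pathway genes, 4 were higher and 0 lower (4 and 1 adjusted over the list alone). Of 22 cell cycle genes, 4 were higher and 1 lower (7 and 2 adjusted over the list alone). Among 35 visceral endoderm genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone), and no list passed camera. The FGF members were Fgf15 (2.12 ± 0.46), Fgf5 (1.33 ± 0.27), Fgfr1 (1.12 ± 0.33) and Fgf3 (1.01 ± 0.33). In all, 1729 of 11351 genes differed, 1430 higher and 299 lower in P, with a median of 0.17. That direction turned with the scaling: an equal sum gave 1026 higher and 467 lower, and equal medians 416 higher and 2082 lower with a median of -0.34, where the FGF list had 2 higher and 4 lower, the core and primed pluripotency list 1 and 2, and the cell cycle list 0 and 6. A fit of the E5.5 embryos alone gave 0 calls, and leaving out embryo 2 gave 2612, with the embryo that remained assumed to vary like the others.

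At E6.0 limma called 0 genes, with 1520 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0654. Mixl1 was at 0.961 ± 1.16 FPKM in P and 1.26 ± 0.685 in A. Otx2 differed by -0.86 ± 0.28 and Ttr, which encodes the carrier transthyretin of the visceral endoderm, by -1.34 ± 0.44. Camera passed 7 lists at its preset correlation and 0 with an estimated one. Adjusted over the list alone, 8 of 18 glycolysis, 5 of 35 visceral endoderm, 4 of 21 core and primed pluripotency and 3 of 15 definitive endoderm genes were lower in P. On the same count 4 of 10 decidua and blood and 3 of 12 cardiac and lateral mesoderm genes were higher, 1 mesenchymal gene was higher, 1 naive pluripotency gene lower, and 1 blood and endothelium gene passed each way. With an estimated correlation the adjusted p was 0.355 for glycolysis, 0.757 for visceral endoderm and 0.184 for decidua and blood. Without embryo 1 or 2 the count was 6 or 462, with the embryo that remained assumed to vary like the others.

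At E7.0, genes of the streak again differed between P and A. T was higher in P by 5.94 ± 0.52 (SE, n = 2, adjusted p = 7.33e-06), Mixl1 by 5.72 ± 0.41 and Mesp1 by 5.26 ± 0.84, with Mesp1 at 172 ± 88.1 FPKM in P and 0.442 ± 0.445 in A. Cyp26a1, which breaks down retinoic acid, was at 122 ± 23.3 against 2.07 ± 2.83 FPKM, and Lefty2 at 84.8 ± 33.3 against 0.233 ± 0.329. Sox2 fell by 2.82 ± 0.47 toward P (adjusted p = 0.00193), Pou3f1 by 2.69 ± 0.35 and Utf1 by 3.61 ± 0.37. The A level of T, 56.2 ± 79.4 FPKM, rested on section 1 of embryo 2, whose A library held 437 FPKM.

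Of 11351 genes, 340 differed at E7.0, 193 higher and 147 lower in P, and camera passed 13 lists at its preset correlation and 6 with an estimated one. Of 30 primitive streak genes, 25 were higher and 0 lower (28 and 0 adjusted over the list alone, adjusted p = 0.00232 with an estimated correlation). Among 19 nascent and paraxial mesoderm genes, 10 were higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 0.0123 with an estimated correlation), with Mesp2 (3.13 ± 0.31) and Tbx6 (2.41 ± 0.42). Of 25 WNT pathway genes, 17 were higher and 1 lower (21 and 1 adjusted over the list alone, adjusted p = 0.00167 with an estimated correlation), with Wnt3a (2.41 ± 0.32) and the antagonist Dkk1 (2.59 ± 0.50). Among 19 FGF pathway genes, 7 were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.0191 with an estimated correlation), with Fgf8 (3.62 ± 0.48) and Fgf4 (2.22 ± 0.45). Of 20 epithelial genes, 0 were higher and 6 lower (0 and 10 adjusted over the list alone, adjusted p = 0.0308 with an estimated correlation), with the tight junction genes Cldn6, at 47.4 ± 9.84 against 167 ± 37.8 FPKM, and Cldn7 (-1.93 ± 0.30). Among 11 anterior epiblast and neural ectoderm genes, 0 were higher and 5 lower (0 and 6 adjusted over the list alone, adjusted p = 0.0191 with an estimated correlation). Of 20 mesenchymal genes, 6 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.366 with an estimated correlation), with Fn1 (1.96 ± 0.32) and Cdh2 (1.21 ± 0.23). Pou5f1 differed by 0.17 ± 0.29 and Otx2 by -0.91 ± 0.28, and neither passed. An equal sum gave 169 higher and 171 lower and equal medians 176 and 199. Leaving out embryo 1 or 2 gave 119 or 121 calls with the embryo that remained assumed to vary like the others, and a fit of the E7.0 embryos alone gave 0.

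At E7.5, P and A were compared in embryos 3 to 6. In embryos 4 to 6, and at E7.0, only sections 3, 6 and 9 entered, and section 1 in E7.0 embryo 2, because A had libraries in no others. T was at 467 ± 303 FPKM in P against 19.0 in A, a difference of 6.38 ± 0.37 (SE, n = 4, adjusted p = 2.43e-09, higher in 4 of 4). Hoxb1 was higher in P by 5.95 ± 0.22, Cdx1 by 5.12 ± 0.23 and Cdx2 by 4.27 ± 0.23; these genes pattern the posterior axis. Otx2, which specifies the anterior head, fell by 4.10 ± 0.20 toward P, from 29.5 ± 9.16 to 0.671 ± 0.657 FPKM, Sox2 by 2.22 ± 0.33 and the forebrain factors Hesx1 and Six3 by 2.57 ± 0.33 and 1.62 ± 0.13. Aldh1a2, which makes retinoic acid, was higher in P by 3.74 ± 0.35.

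Of 11351 genes, 1601 differed at E7.5, 1209 higher and 392 lower in P, with a median of 0.15; an equal sum gave 740 and 578 with a median of 0.04, and equal medians 574 and 684 with a median of -0.02. Camera passed 15 lists at its preset correlation and 6 with an estimated one. Among 11 Hox and Cdx genes, 10 were higher and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 0.00324 with an estimated correlation). Among 30 primitive streak genes, 24 were higher and 0 lower (25 and 1 adjusted over the list alone, adjusted p = 0.0162 with an estimated correlation). Among 19 nascent and paraxial mesoderm genes, 14 were higher and 0 lower (15 and 0 adjusted over the list alone, adjusted p = 0.00643 with an estimated correlation), with Tbx6 (4.54 ± 0.30), Dll3 (3.62 ± 0.25) and Mesp1 (2.67 ± 0.60). Of 25 WNT pathway genes, 21 were higher and 2 lower (21 and 2 adjusted over the list alone, adjusted p = 0.00313 with an estimated correlation), with Wnt3a (4.49 ± 0.23) and Rspo3 (3.92 ± 0.29). Among 19 FGF pathway genes, 13 were higher and 2 lower (13 and 2 adjusted over the list alone, adjusted p = 0.00324 with an estimated correlation), with the feedback genes Dusp6 (3.40 ± 0.18) and Spry2 (2.82 ± 0.17). Of 11 anterior epiblast and neural ectoderm genes, 0 were higher and 8 lower (0 and 8 adjusted over the list alone, adjusted p = 0.00313 with an estimated correlation). Among 12 retinoic acid genes, 7 were higher and 0 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0536 with an estimated correlation). Of 20 epithelial genes, 1 was higher and 8 lower (1 and 8 adjusted over the list alone, adjusted p = 0.0704 with an estimated correlation), with Cldn6 at 16.5 ± 9.03 FPKM in P and 168 ± 82.3 in A. Among 13 anterior visceral endoderm genes, 2 were higher and 5 lower (2 and 5 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation); its lower members Otx2, Hesx1 and Sfrp1 (-3.50 ± 0.23) are also expressed in anterior ectoderm. Of 20 mesenchymal genes, 11 were higher and 1 lower (13 and 1 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation), with Vim (2.45 ± 0.29). Among 22 cell cycle genes, 7 were higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 0.227 with an estimated correlation). Markers of another tissue moved with P: of 13 extra-embryonic ectoderm and trophoblast genes, 7 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0156, and adjusted p = 0.0622 with an estimated correlation). Pou5f1 was higher in P by 0.97 ± 0.20, Nanog differed by -0.05 ± 0.24 and Ttr by 0.92 ± 0.31. Without embryo 5 the count was 1011, and without E6.5 embryos 1 to 4 and E7.5 embryo 3, from which no endoderm libraries came, it was 556. Otx2 lies on chromosome 14, 48657677 to 48673819, Hoxb1 on chromosome 11, 96365752 to 96368256, and Sox2 on chromosome 3, 34650405 to 34652461.

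Whether the difference between P and A itself changed was tested between E7.5 (n = 4) and E6.5 (n = 6). For Hoxb1 it went from 0.37 at E6.5 to 5.95 at E7.5, a change of 5.57 ± 0.28 (SE, adjusted p = 1.51e-09). For T it went from 2.43 to 6.38 and for Mixl1 from 3.36 to 6.07. Otx2 went from -0.40 to -4.10, and the chemokine gene Cxcl12 from 0.74 to -3.12. Gsc and Foxa2, higher in P at E6.5, went from 1.95 to -0.37 and from 1.44 to -0.77.

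In this test 465 of 11351 genes changed, 359 upward and 106 downward, with a median of 0.16; an equal sum gave 291 and 168 with a median of 0.05, and equal medians 242 and 142. Camera passed 16 lists at its preset correlation and 7 with an estimated one. Of 11 Hox and Cdx genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.00288 with an estimated correlation). Among 19 nascent and paraxial mesoderm genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.0119 with an estimated correlation), with Tbx6 (4.44 ± 0.39) and the segmentation genes Hes7 (4.47 ± 0.47) and Msgn1 (4.28 ± 0.54). Of 19 FGF pathway genes, 12 rose and 2 fell (14 and 2 adjusted over the list alone, adjusted p = 0.00288 with an estimated correlation), with Fgf15 (3.91 ± 0.42), Fgf4 (3.47 ± 0.41) and Dusp6 (3.06 ± 0.24). Among 25 WNT pathway genes, 15 rose and 1 fell (17 and 2 adjusted over the list alone, adjusted p = 0.00288 with an estimated correlation), with Wnt3a (4.11 ± 0.29). Of 12 retinoic acid genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.0315 with an estimated correlation). Among 30 primitive streak genes, 16 rose and 2 fell (17 and 4 adjusted over the list alone, adjusted p = 0.142 with an estimated correlation). Of 11 anterior epiblast and neural ectoderm genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone, adjusted p = 0.00288 with an estimated correlation). Among 13 anterior visceral endoderm genes, 0 rose and 6 fell (1 and 7 adjusted over the list alone, adjusted p = 0.0159 with an estimated correlation). The changes of Mesp1 (0.52 ± 0.77), Eomes (-0.65 ± 0.41) and Sox2 (-1.28 ± 0.42) did not pass. Leaving out E7.5 embryo 5 gave 304 calls, and leaving out E6.5 embryos 1 to 4 and E7.5 embryo 3 gave 46.

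Levels of A and P together were then compared between stages, on libraries rescaled to a sum of 1000000. Each embryo's values stand in a table of its own, and the tables may have been normalised separately, so these levels carry less weight than differences within an embryo. From E5.5 and E6.0 (n = 4) to E6.5 (n = 6), Fgf8 rose by 3.32 ± 0.43 (SE, adjusted p = 5.49e-04), T by 2.51 ± 0.41 and Mixl1 by 2.47 ± 0.34, and Mesp1 went from listed at 0 in all 4 embryos to 29.8 ± 12.2 per 1000000. Dppa4, Dppa2 and Dppa5a, genes tied to pluripotent cells, fell by 3.79 ± 0.42, 2.95 ± 0.42 and 2.50 ± 0.41. Genes of the visceral endoderm fell as well: Ttr went from 122 ± 96.7 to 9.10 ± 3.62 per 1000000 and the apolipoprotein gene Apoa1 from 237 ± 144 to 25.0 ± 12.0.

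Of the genes tested, 495 differed, 392 higher and 103 lower at E6.5, with a median of 0.33; FPKM as deposited gave 306 and 88 with a median of 0.35, and equal medians 229 and 423 with a median of -0.17. Camera passed 11 lists at its preset correlation and 2 with an estimated one. Of 35 visceral endoderm genes, 0 were higher and 17 lower (1 and 25 adjusted over the list alone, adjusted p = 0.0391 with an estimated correlation). Among 7 naive pluripotency genes, 0 were higher and 3 lower (0 and 5 adjusted over the list alone, adjusted p = 0.0391 with an estimated correlation). Of 30 primitive streak genes, 15 were higher and 0 lower (18 and 1 adjusted over the list alone, adjusted p = 0.199 with an estimated correlation), with Snai1 (1.95 ± 0.42), Wnt3 (2.05 ± 0.32) and Eomes (1.79 ± 0.42). Among 17 NODAL pathway genes, 8 were higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.423 with an estimated correlation), with Nodal (1.52 ± 0.37), Foxh1 (2.60 ± 0.69) and Lefty2 (2.20 ± 0.44). Pou5f1 differed by 0.97 ± 0.36, Nanog by -1.12 ± 0.41 and Sox2 by -0.44 ± 0.36, and none passed. The count moved with most embryos: it was 58 or 40 without E5.5 embryo 1 or 2, 2212 or 2112 without E6.0 embryo 1 or 2, and 174, 197, 83, 101 or 235 without E6.5 embryo 1, 2, 3, 4 or 5, and 0 without E6.5 embryos 1 to 4. Ttr lies on chromosome 18, 20665280 to 20674321.

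**Figure D3:**
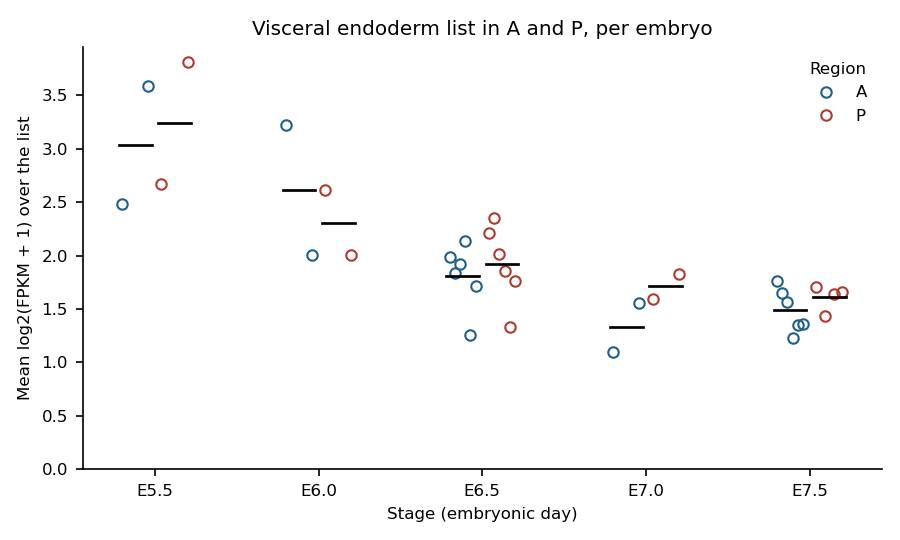
Mean log2(FPKM + 1) over 39 visceral endoderm genes in regions A and P of each embryo by stage, with black lines at the stage means. In E6.0 embryo 2, whose visceral endoderm was captured apart, A and P both stood at 2.00 and the visceral endoderm libraries at 4.07.

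From E6.5 (n = 6) to E7.5 (n = 4), genes of the posterior axis rose. T went from 27.5 ± 10.3 to 603 ± 141 per 1000000 (4.03 ± 0.41, adjusted p = 1.27e-06), Hoxb1 rose by 3.73 ± 0.32, Cdx1 by 3.74 ± 0.36, Tbx6 by 3.25 ± 0.31 and the galanin gene Gal by 4.59 ± 0.45. Tdgf1 fell by 4.71 ± 0.41, Eomes by 3.10 ± 0.42, Nodal by 2.89 ± 0.37 and Fgf5, a gene of the primed epiblast, by 2.63 ± 0.31. The metallothionein genes Mt1 and Mt2 fell by 3.26 ± 0.40 and 3.09 ± 0.45. Pou5f1 (-0.25 ± 0.36), Nanog (0.40 ± 0.41) and Sox2 (0.30 ± 0.36) did not pass.

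In all, 435 genes differed between these stages, 335 higher and 100 lower at E7.5, with a median of 0.22. FPKM as deposited gave 124 and 164 with a median of -0.22, and equal medians 142 and 289 with a median of -0.18. Camera passed 16 lists at its preset correlation and 7 with an estimated one. Of 11 Hox and Cdx genes, 10 were higher and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 0.00544 with an estimated correlation). Among 25 WNT pathway genes, 15 were higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 0.0392 with an estimated correlation), with Wnt3a (2.81 ± 0.28). Of 19 nascent and paraxial mesoderm genes, 9 were higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.0471 with an estimated correlation), with Dll1 (3.08 ± 0.24) and Msgn1 (2.96 ± 0.37). Among 17 NODAL pathway genes, 0 were higher and 11 lower (1 and 12 adjusted over the list alone, adjusted p = 0.00323 with an estimated correlation), with Lefty1 (-2.22 ± 0.35) and Smad7 (-2.29 ± 0.36). Of 21 core and primed pluripotency genes, 1 was higher and 9 lower (2 and 10 adjusted over the list alone, adjusted p = 0.0471 with an estimated correlation), with Utf1 (-3.99 ± 0.36) and Otx2 (-2.65 ± 0.39). Among 10 left-right genes, 1 was higher and 5 lower (2 and 6 adjusted over the list alone, adjusted p = 0.0471 with an estimated correlation). Of 11 anterior epiblast and neural ectoderm genes, 2 were higher and 3 lower (2 and 5 adjusted over the list alone, adjusted p = 0.0468 with an estimated correlation). Without E7.5 embryo 5 the count was 281, and without E6.5 embryos 1 to 4 and E7.5 embryo 3 it was 30.

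Endoderm (EA and EP) was compared with the epiblast regions A and P of the same sections in 6 embryos, 2 each at E6.5, E7.0 and E7.5. Genes of visceral endoderm led the difference. Spink3, a trypsin inhibitor gene, was at 9776 ± 4536 FPKM in endoderm and 64.9 ± 49.8 in epiblast, and Ttr at 567 ± 372 and 2.74 ± 2.44. Apoa1 was higher by 6.97 ± 0.16 (SE, n = 6, adjusted p = 2.27e-18), Afp, which encodes alpha-fetoprotein, by 5.09 ± 0.22, and the endoderm factors Sox17, Gata4 and Foxa2 by 2.75 ± 0.16, 2.55 ± 0.15 and 2.60 ± 0.19. Pou5f1 fell by 3.59 ± 0.16 toward endoderm, from 293 ± 149.7 to 38.3 ± 27.4 FPKM, and Slc7a3 by 4.25 ± 0.16.

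Of 10307 genes, 7086 differed, 1114 higher and 5972 lower in endoderm. The median of all genes was -0.47, and the split rested on it: an equal sum gave 1310 higher and 4552 lower, and equal medians 2636 and 2665 with a median of 0.01. Camera passed 19 lists at its preset correlation and 0 with an estimated one, where only 3 residual degrees of freedom were left. Among 38 visceral endoderm genes, 37 were higher and 0 lower (37 and 0 adjusted over the list alone, adjusted p = 0.0906 with an estimated correlation). Of 16 parietal endoderm genes, 15 were higher and 0 lower (15 and 0 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), with Col4a1 (3.87 ± 0.17), Sparc (2.84 ± 0.17) and Krt8 (3.66 ± 0.17). Among 18 definitive endoderm genes, 15 were higher and 2 lower (15 and 2 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation). Of 13 anterior visceral endoderm genes, 10 were higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.083 with an estimated correlation), with Cer1 (3.32 ± 0.15) and Dkk1 (2.30 ± 0.21). Among 16 BMP pathway genes, 9 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.083 with an estimated correlation), with Bmp2 (2.45 ± 0.19). Of 21 core and primed pluripotency genes, 0 were higher and 17 lower (0 and 17 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation). Among 18 glycolysis genes, 1 was higher and 16 lower (1 and 16 adjusted over the list alone, adjusted p = 0.414 with an estimated correlation), with Eno1 (-3.79 ± 0.21) and Ldha (-1.38 ± 0.11). Of 22 cell cycle genes, 0 were higher and 20 lower (0 and 21 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation), with Ccnb1 (-1.43 ± 0.15). Among 30 primitive streak genes, 7 were higher and 12 lower (7 and 12 adjusted over the list alone), which equal medians turned to 14 higher and 7 lower. T fell by 1.25 ± 0.17, while Mesp1 (0.22 ± 0.19) and Eomes (-0.06 ± 0.15) did not pass; Eomes passed as higher in endoderm with an equal sum (0.45) and with equal medians (0.42).

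Markers of other tissues moved with the endoderm. Of 15 extra-embryonic ectoderm and trophoblast genes, 11 were higher and 0 lower (11 and 0 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation), with the placental lactogen gene Prl3d1 at 444 ± 421 FPKM in endoderm and 1.13 ± 0.901 in epiblast. Among 7 maternal decidua and blood genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation), with the adult globin gene Hba-a1 at 2911 ± 2964 and 87.4 ± 60.7 FPKM; Hba-a1 and Hba-a2 are near-identical copies, so the division of reads between them is uncertain. The endoderm libraries of the E6.5 embryos had 5199 and 6865 genes at 1 FPKM or more, against 7910 and 9215 in their epiblast libraries, and 5.13 and 13.0% of their FPKM sum came from the ribosomal RNA gene Rn45s, against 0.894 and 3.46%. Apoa1 lies on chromosome 9, 46228580 to 46230466, Sox17 on chromosome 1, 4490931 to 4497354 and Pou5f1 on chromosome 17, 35506018 to 35510772.

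**Figure D4:**
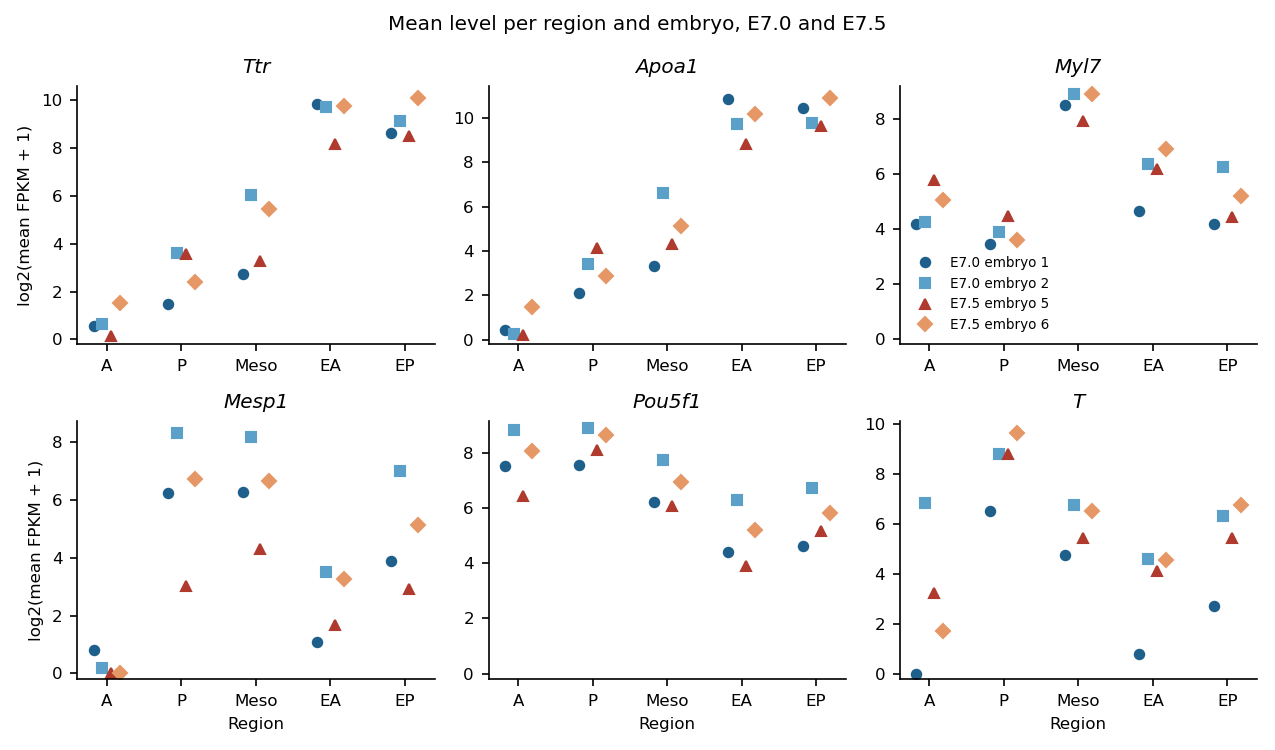
log2(mean FPKM + 1) of Ttr, Apoa1, Myl7, Mesp1, Pou5f1 and T in A, P, mesoderm (M, or MA and MP), EA and EP of E7.0 embryos 1 and 2 and E7.5 embryos 5 and 6. Ttr and Apoa1 stand highest in EA and EP, Myl7 in mesoderm, and T in P.

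The endoderm contrast was then compared between E7.5 and E6.5, with 2 embryos each. Trh, the gene of thyrotropin-releasing hormone, went from -4.45 at E6.5 to 3.17 at E7.5 (7.63 ± 1.41, SE, adjusted p = 0.0189). Sox17 went from 1.23 to 3.55, Foxa2 from 1.55 to 3.47 and Krt18, a keratin gene, from 1.18 to 4.24. Mixl1 went from 0.08 to -2.05, Cyp26a1 from 3.76 to 1.82 and Cdx1 from -0.11 to -1.90. Foxa2 did not pass with an equal sum or equal medians, Sox17 and Trh not with equal medians and Cdx1 not with an equal sum. Ttr (0.19 ± 0.38) and T (-0.27 ± 0.43) did not pass. At E7.5 the endoderm libraries of the embryos had 9096 and 8966 genes at 1 FPKM or more, against 9237 and 9361 in epiblast, where at E6.5 they had 5199 and 6865 against 7910 and 9215; Rn45s made up 0.806 and 7.18% of their FPKM sum, against 5.13 and 13.0% at E6.5.

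The change was called in 3807 of 10307 genes, 3774 upward and 33 downward, with a median of all genes of 0.78. It rested on the scaling: an equal sum gave 514 upward and 18 downward with a median of 0.52, and equal medians 174 and 161 with a median of -0.20. Camera passed 10 lists at its preset correlation and 0 with an estimated one. Of 20 epithelial genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation), with Cldn6 (3.11 ± 0.49). Among 18 definitive endoderm genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone), which equal medians turned to 2 upward and 3 downward. Of 38 visceral endoderm genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), which equal medians turned to 1 each. Among 22 cell cycle genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone). Of 18 glycolysis genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone). With either other scaling 0 cell cycle genes rose. Among 6 Hox and Cdx genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, adjusted p = 0.0691 with an estimated correlation), also 0 with an equal sum. Of 30 primitive streak genes, 6 rose and 8 fell (6 and 8 adjusted over the list alone, adjusted p = 0.0691 with an estimated correlation), with 3 each way under an equal sum. The adult globin gene Hbb-b1 went from -0.06 to 6.71 and the placental Prl2c2 from 0.72 to 4.85; both have near-identical copies, Hbb-b2 and Prl2c3, so the division of reads is uncertain. Without E6.5 embryo 5 or 6 the count was 2289 or 2326 and without E7.5 embryo 5 it was 1409, with the embryo that remained assumed to vary like the others.

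Mesoderm was compared with the P side of the same sections in 4 embryos, 2 each at E7.0 and E7.5. Myl7, a heart myosin light chain gene, was at 396 ± 116 FPKM in mesoderm and 14.3 ± 5.59 in P, a difference of 4.04 ± 0.33 (SE, n = 4, adjusted p = 7.14e-04, higher in 4 of 4). Gata6 and Twist1, transcription factors of mesoderm, were higher by 1.87 ± 0.17 and 1.72 ± 0.20, the VEGF receptor gene Kdr by 1.39 ± 0.15 and the segmentation gene Ripply2 by 2.53 ± 0.56. T fell by 3.16 ± 0.11, Mixl1 by 3.33 ± 0.15, Fst by 3.37 ± 0.09 and Cdh1, which encodes E-cadherin, by 2.49 ± 0.10. Mesp1 differed by 0.52 ± 0.28 and did not pass.

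Of 9883 genes, 4305 differed, 390 higher and 3915 lower in mesoderm, with a median of all genes of -0.24. An equal sum gave 411 and 1463 with a median of -0.15, and equal medians 1059 and 948. Camera passed 17 lists at its preset correlation and 0 with an estimated one. Among 18 cardiac, lateral and extra-embryonic mesoderm genes, 14 were higher and 0 lower (14 and 0 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation), with Gata4 (1.43 ± 0.12) and Hand1 (0.83 ± 0.11). Of 18 mesenchymal genes, 9 were higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation), with Fn1 (1.13 ± 0.11) and Cdh2 (0.99 ± 0.09). Among 14 BMP pathway genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone, adjusted p = 0.141 with an estimated correlation). Of 30 primitive streak genes, 6 were higher and 19 lower (6 and 19 adjusted over the list alone, adjusted p = 0.961 with an estimated correlation). Among 24 WNT pathway genes, 2 were higher and 18 lower (2 and 20 adjusted over the list alone, adjusted p = 0.565 with an estimated correlation), with Wnt3a (-2.91 ± 0.30). Of 9 Hox and Cdx genes, 0 were higher and 7 lower (0 and 7 adjusted over the list alone, adjusted p = 0.662 with an estimated correlation), with Cdx1 (-2.87 ± 0.22). Among 18 glycolysis genes, 0 were higher and 15 lower (0 and 15 adjusted over the list alone, adjusted p = 0.265 with an estimated correlation). Of 18 core and primed pluripotency genes, 1 was higher and 11 lower (1 and 12 adjusted over the list alone), with Pou5f1 (-1.77 ± 0.08). Endoderm genes were higher in the same libraries, 17 of 31 visceral endoderm genes with 2 lower (19 and 2 adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), with Spink3 at 669.8 ± 522 FPKM in mesoderm and 138 ± 104 in P and Ttr at 30.3 ± 28.2 and 7.70 ± 5.24. Among 6 maternal decidua and blood genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.265 with an estimated correlation), with the adult globin genes Hbb-b1 (2.75 ± 0.10) and Hba-a1 (2.12 ± 0.25) higher in 4 of 4 embryos. Of 10 extra-embryonic ectoderm and trophoblast genes, 4 were higher and 3 lower (4 and 3 adjusted over the list alone, adjusted p = 0.417 with an estimated correlation). Without E7.5 embryo 5 or 6 the count was 1879 or 2518, with the E7.5 embryo that remained assumed to vary like the others. Myl7 lies on chromosome 11, 5896637 to 5898782 and Cdh1 on chromosome 8, 106603351 to 106670246.

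Against endoderm, the same mesoderm libraries were higher in Mesp1, at 121 ± 117 against 25.4 ± 29.6 FPKM (2.77 ± 0.13, SE, n = 4, adjusted p = 9.83e-05), Lefty2 (3.27 ± 0.18), the apelin receptor gene Aplnr (2.93 ± 0.15) and Myl7 (2.73 ± 0.24). They were lower in Ttr, at 30.3 ± 28.2 against 667 ± 269 FPKM, in Apoa1 (-4.93 ± 0.42), Sox17 (-2.33 ± 0.14) and Foxa2 (-2.04 ± 0.21), each lower in 4 of 4 embryos. Of 9910 genes, 3906 differed, 2465 higher and 1441 lower, with a median of 0.17, and the scalings kept more genes higher than lower, at 2349 and 1662 with an equal sum and 3141 and 1666 with equal medians. Camera passed 14 lists at its preset correlation and 0 with an estimated one.

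Among 20 nascent and paraxial mesoderm genes, 18 were higher and 1 lower (19 and 1 adjusted over the list alone, adjusted p = 0.647 with an estimated correlation), with Dll3 (3.04 ± 0.20) and Tbx6 (1.28 ± 0.18). Of 28 primitive streak genes, 17 were higher and 3 lower (18 and 4 adjusted over the list alone, adjusted p = 0.647 with an estimated correlation), with T (1.61 ± 0.19). Among 22 cell cycle genes, 16 were higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 0.647 with an estimated correlation). Of 38 visceral endoderm genes, 0 were higher and 37 lower (0 and 37 adjusted over the list alone). Among 18 definitive endoderm genes, 2 were higher and 14 lower (2 and 14 adjusted over the list alone). Of 18 epithelial genes, 0 were higher and 17 lower (0 and 17 adjusted over the list alone), with Cldn6 (-3.89 ± 0.17) and Cldn7 (-3.46 ± 0.13). Markers of other tissues were lower as well, 10 of 15 trophoblast genes with 2 higher (12 and 2 adjusted over the list alone), with Prl3d1 (-5.27 ± 0.31), and 6 of 6 decidua and blood genes with 0 higher (6 and 0), with Hba-a1 (-3.00 ± 0.24). Each of these 5 lower lists had adjusted p = 0.603 with an estimated correlation, where only 2 residual degrees of freedom were left. Without E7.5 embryo 5 or 6 the count was 2200 or 1790, with the E7.5 embryo that remained assumed to vary like the others.

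Within the endoderm, posterior (EP) and anterior (EA) libraries of the same sections were compared in 6 embryos. Cer1, a secreted antagonist of NODAL, BMP and WNT made by the anterior visceral endoderm, fell by 3.51 ± 0.19 toward EP (SE, n = 6, adjusted p = 6.55e-06, lower in 6 of 6), from 105 ± 80.8 to 11.8 ± 12.1 FPKM. Hhex and Hesx1, transcription factors of the anterior endoderm, fell by 2.13 ± 0.20 and 2.51 ± 0.20, Otx2 by 1.93 ± 0.32 and Dkk1 by 2.02 ± 0.25. Mixl1 was higher in EP by 2.60 ± 0.25, T by 2.03 ± 0.21 and Mesp1 by 1.96 ± 0.30, each in 6 of 6 embryos.

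Of 10147 genes, 152 differed, 90 higher and 62 lower in EP; an equal sum gave 37 and 47 and equal medians 43 and 69. Camera passed 14 lists at its preset correlation and 0 with an estimated one. Among 13 anterior visceral endoderm genes, 0 were higher and 9 lower (0 and 9 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation), with Sfrp5 (-1.46 ± 0.17) and Lefty1 (-1.73 ± 0.25, 5 of 6 embryos). Of 18 definitive endoderm genes, 1 was higher and 6 lower (1 and 9 adjusted over the list alone, adjusted p = 0.0988 with an estimated correlation). Among 39 visceral endoderm genes, 7 were higher and 0 lower (17 and 1 adjusted over the list alone, adjusted p = 0.532 with an estimated correlation), with Afp (1.37 ± 0.25) and Apoc2, higher by 2.38 ± 0.45 in 5 of 6. Of 27 primitive streak genes, 13 were higher and 0 lower (19 and 1 adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). Among 18 nascent and paraxial mesoderm genes, 7 were higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 0.341 with an estimated correlation), with Tbx6 (1.40 ± 0.24, 5 of 6). Of 21 WNT pathway genes, 8 were higher and 3 lower (14 and 3 adjusted over the list alone, adjusted p = 0.517 with an estimated correlation), with Rspo3 (1.68 ± 0.23) higher and Sfrp1 (-2.65 ± 0.20) lower. Msx1as, antisense to Msx1 and not separable from it without strand, was higher by 1.45 ± 0.20. Ttr (0.37 ± 0.26), Foxa2 (-0.23 ± 0.19) and Sox17 (-0.24 ± 0.23) did not pass. Without E6.5 embryo 5 or 6 the count was 683 or 516, without E7.0 embryo 2 it was 32 and without E7.5 embryo 5 it was 79. Cer1 lies on chromosome 4, 82881751 to 82885148.

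Posterior (MP) and anterior (MA) mesoderm were compared in 2 embryos at E7.5. T was higher in MP by 3.78 ± 0.24 (SE, n = 2, both embryos), Hoxb1 by 3.69 ± 0.25, Mixl1 by 3.51 ± 0.22, and the lateral mesoderm factor Foxf1 by 1.07 ± 0.22. Myl7 fell by 2.84 ± 0.23 toward MP, from 627 ± 261 to 107 ± 85.5 FPKM, Cer1 by 3.23 ± 0.24, Sfrp1 by 3.33 ± 0.24, Otx2 by 2.26 ± 0.23 and the craniofacial homeobox gene Alx1 by 2.28 ± 0.22. Mesp1 (0.56 ± 0.24) and Eomes (-0.13 ± 0.22) did not pass.

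Of 9322 genes, 321 differed, 152 higher and 169 lower in MP, from a fit with 1 residual degree of freedom, whose p-values rest on the spread shared among genes. Camera passed 19 of 29 lists at its preset correlation and 0 with an estimated one, where each list named here except the cardiac one had adjusted p = 0.626 with an estimated correlation. Among 8 Hox and Cdx genes, 6 were higher and 0 lower (7 and 0 adjusted over the list alone). Of 26 primitive streak genes, 19 were higher and 1 lower (21 and 2 adjusted over the list alone). Among 22 WNT pathway genes, 16 were higher and 1 lower (17 and 2 adjusted over the list alone), with Rspo3 (2.57 ± 0.30). Of 19 cardiac, lateral and extra-embryonic mesoderm genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone), which an equal sum turned to 0 and 1, with Hand1 (0.86 ± 0.23) and Bmp4 (0.86 ± 0.22) higher. Among 9 anterior visceral endoderm genes, 0 were higher and 6 lower (0 and 8 adjusted over the list alone). Of 14 definitive endoderm genes, 1 was higher and 8 lower (1 and 9 adjusted over the list alone). Among 13 epithelial genes, 0 were higher and 6 lower (0 and 6 adjusted over the list alone), with Krt8 (-1.41 ± 0.24), Krt18 (-1.31 ± 0.24) and Cldn6 (-1.42 ± 0.24). Of 28 visceral endoderm genes, 0 were higher and 8 lower (0 and 10 adjusted over the list alone). Among 7 anterior epiblast and neural ectoderm genes, 0 were higher and 5 lower (0 and 7 adjusted over the list alone). Of 6 maternal decidua and blood genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone), and of 9 extra-embryonic ectoderm and trophoblast genes 3 were higher and 0 lower (3 and 0 adjusted over the list alone).

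Right (R) and left (L) libraries were compared in 3 embryos, 2 at E7.0 and 1 at E7.5, to ask whether the sides of the epiblast differ. Libraries coded R1 and R2 were averaged within a section as R, and those coded L1 and L2 as L. By limma 0 of 9926 genes did, with 456 at an unadjusted p under 0.05 and a smallest adjusted p of 0.785. T differed by -0.76 ± 0.28 (SE, n = 3), lower in R in 3 of 3 embryos, Nanog by -0.52 ± 0.28, Mesp1 by -0.42 ± 0.30, Mixl1 by 0.17 ± 0.24 and Otx2 by 0.06 ± 0.30, and none passed (adjusted p = 0.785 for T). Among 7 left-right genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone) and camera adjusted p = 0.83. On values simulated for these 3 embryos, 65% of genes with a log2 difference of 1 were found and 100% of those with 2. Without E7.0 embryo 1 or 2 or E7.5 embryo 3, limma called 3, 30 or 16 genes. In the R library of section 2 of E7.5 embryo 3, 69.4% of the FPKM sum came from the small RNA gene Scarna3b; without it 0 genes were called and T differed by -0.63. The median of all genes was -0.18.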

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

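The tests of the unshared part of the E5.5 difference, of equal library medians, of embryonic beta globin, of genes of like level and without E6.5 embryos 5 and 6, and the scalings and expected shares of the sign at E6.0, were chosen after the results were seen. Of 119 groups of values per embryo, 6 had an embryo far from the others, and with so many groups some may arise by chance. E6.5 embryo 5 had a T difference between EP and EA of 0.55 where the others had 2.02 to 2.78, and a Nanog difference of -0.75 where the others had 0.03 to 0.31. E7.0 embryo 1 had a Ttr difference of -1.54 there, against 0.16 to 1.16 in the others. The Pou3f1 slope in P of E6.5 embryo 3 was -3.75, against -1.86 to -1.70. In A and P of E7.5 embryo 3, the log2 level of Otx2 was 2.93 and that of Nanog 4.54, against 3.64 to 3.72 and 5.70 to 5.82.

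Effects that differed between stages were the 465 genes of the change of P minus A and the 3807 of the change of endoderm minus epiblast. Signals outside the comparisons were found in 3 places. The 4 VE libraries of E6.0 embryo 2 held a mean of 114.9 FPKM of Ttr, against 9.75 in its 8 A and P libraries. In E7.5 embryo 4, the 18 E1 and E2 libraries held 137.8 FPKM of Ttr, from 0 to 853, against 1.33 in 13 A and P libraries, and the 18 M1 and M2 libraries 76.8 FPKM of Myl7, from 0 to 170.1, against 11.3.

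P minus A at E5.5 gave 1729 genes from 2 embryos. Against a difference that lasts, 33.1% of them had the same sign at E6.0, where 43.7% would follow from the shares of all genes in each direction; with an equal sum it was 47.4% against 52.3%, and with equal medians 46.6% against 52.0%. The difference between the 2 embryos scaled by 0.5, which holds no shared effect and stood in for their mean, gave 977 genes, and the median standard deviation of a gene between embryos was 0.456 at E5.5 against 0.244 at E6.5; equal library medians made 16.7% of the called genes higher in P. A candidate explanation is that the spread shared with later stages is too small for E5.5, with library scaling adding to it; a difference between A and P that is present at E5.5 alone was not tested. Across genes, which are not independent replicates, the differences of the 2 embryos correlated by 0.0436.

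Adult globin genes were higher in EA and EP than in A and P; at E7.5 Hba-a1 stood at 7417 FPKM against 663 in embryo 5 and at 940 against 38.0 in embryo 6, with 902 and 207 in MA and MP of these embryos. The embryo's own yolk sac red cells are argued against by Hbb-y and Hbb-bh1, which made up 0.00525% of the beta globin FPKM in EA and EP of E7.5. In RNA of maternal red cells alpha and beta globin would vary together, and the standard deviation of their log2 ratio was 0.315 times that of alpha (median of 6 embryos, 0.193 to 0.733). Maternal red cells on the outer side of the embryo are a candidate source, a hypothesis from the same data. Expression by the captured endoderm cells cannot be told apart: the globins' spread between libraries stood at percentile 87.2 of genes of like level, but 1 to 18 such genes existed.

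Visceral endoderm genes were higher in A and P before gastrulation than at E6.5. Of 29 genes at least 8 times higher in EA and EP of E6.5 than in its epiblast, 100% were lower at E6.5, with a median of -1.81, against 26.9% of the other genes, with an equal sum. The E6.5 embryos 5 and 6 that chose these genes are also among the 6 compared; without them 100% were lower, with a median of -1.75, against 34.3% of the other genes. Depth is argued against by genes of like level: in 94.3% of 35 genes of the visceral endoderm list the change lay below the median of other genes of like level, with a median difference of -1.62 under an equal sum or equal medians and -1.36 with FPKM as deposited. The median of all genes itself turned with the scaling, from 0.33 with an equal sum to -0.17 with equal medians. Expression of these genes by epiblast cells is argued against by E6.0 embryo 2, whose visceral endoderm was captured apart and whose mean log2 level of the list in A and P was 2.73 on libraries rescaled to a sum of 1000000 (35 tested genes), against 3.75, 4.83 and 3.88 in the other 3 embryos. The earlier A and P captures may therefore hold visceral endoderm cells, a hypothesis with 1 embryo on its far side.

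Chance regroupings were run for counts of at least 3 embryos except the endoderm change. With the signs of whole embryos turned, 1 of 32 splits, the real one, reached 84 genes in P minus A at E6.5 (highest other 0), 152 in EP minus EA (8), 178 in the P slope (1) and 5 in the A slope (2). That is the smallest share that 32 splits can give, so it argues against chance there without excluding it. For the 7086 of endoderm minus epiblast 1 of 32 also reached the count. The highest other, 4967, turned both E7.5 embryos, which reverses the mean of that stage and leaves the spread of the fit unchanged. For P minus A at E7.5, 1 of 8 splits reached 1601 (highest other 5), for mesoderm minus P 1 of 8 reached 4305 (3) and for mesoderm minus endoderm 1 of 8 reached 3906 (0); 4 of 4 reached 0 in R minus L (0), and these splits are too few for a share under 0.05. Over 100 regroupings of embryos between stages, 1 reached the 465 of the change of P minus A (highest other 1), 1 the 435 between E7.5 and E6.5 (67) and 3 the 495 between E6.5 and earlier stages. These shares argue against chance for the change of P minus A and for E7.5 against E6.5. For E6.5 against earlier stages chance is not excluded, since the highest other was 4243. That split exchanged both E6.0 embryos with E6.5 embryos 1 and 2, which points to a structure of the samples.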

How the results depend on the processing

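The alternatives without E6.5 embryos 1 to 4 and E7.5 embryo 3, without E6.5 embryos 5 and 6, without libraries led by 1 gene and without section 1 of E7.0 embryo 2 were chosen after the results were seen; the others were fixed before. Over 17 counts of called genes, 175 alternative values lay within 1.5 times the reported count and 109 did not. Depth limits genes with low values. Except where the setting itself tests fewer genes or embryos, the cause was not tested. Fits of only the stages in the contrast are identical to the reported ones for both mesoderm contrasts, the endoderm means, MP minus MA and R minus L; MP minus MA keeps no residual degrees of freedom without an embryo, and gradients and stage levels have no block to leave out.

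A pseudocount of 0.1 called 39 genes in P minus A at E6.5, 64 in EP minus EA, 1097 between E6.5 and earlier stages and 226 between E7.5 and E6.5; a pseudocount of 5 called 1 in P minus A at E6.0, 1858 in the endoderm change, 8 in the A slope, 247 between E6.5 and earlier stages and 755 between E7.5 and E6.5. With no filter on low values the counts were 49 in P minus A at E6.5, 33 at E6.0, 1273 in the endoderm change, 20 in EP minus EA, 118 in the P slope and 77 between E6.5 and earlier stages. A mean of at least 5 FPKM left 215 in P minus A at E7.0 and 1036 at E7.5, 4470 in endoderm minus epiblast, 2255 in mesoderm minus endoderm, 77 in EP minus EA, 125 in MP minus MA and 193 between E7.5 and E6.5, with fewer genes tested. An equal sum gave 47 in P minus A at E6.5, 532 in the endoderm change, 1874 in mesoderm minus P, 84 in EP minus EA, 134 in MP minus MA, 91 in the P slope and 8 in the A slope; equal medians gave 335 in the endoderm change, 2007 in mesoderm minus P and 9 in the A slope; FPKM as deposited gave 288 between E7.5 and E6.5. Eomes, not called in endoderm minus epiblast, was higher in endoderm by 0.45 with an equal sum and 0.42 with equal medians. All sections of each region gave 2548 in P minus A at E7.5 and 743 in its change, and moderation without trend and robust 290 between E6.5 and earlier stages.

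Only the stages in the contrast gave 290 in P minus A at E6.5, 0 at E5.5, 0 at E7.0, 888 at E7.5 and 967 in its change, 1695 in the P slope, 159 between E6.5 and earlier stages and 900 between E7.5 and E6.5. Without the block on the embryo, the paired contrasts gave 15 in P minus A at E6.5, 7 at E5.5, 63 at E7.0, 395 at E7.5 and 130 in its change, 3592 in endoderm minus epiblast and 7 in its change, 163 in mesoderm minus P, 915 in mesoderm minus endoderm, 38 in EP minus EA, 90 in MP minus MA and 1 in R minus L.

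Leaving out 1 embryo at a time gave from 34 to 61 in P minus A at E6.5, 2061 to 2612 at E5.5, 6 to 462 at E6.0, 119 to 121 at E7.0, 1011 to 1308 at E7.5 and 304 to 432 in its change. The range was 6061 to 6884 in endoderm minus epiblast, 1409 to 3093 in its change, 1879 to 4379 in mesoderm minus P, 1790 to 5753 in mesoderm minus endoderm, 32 to 683 in EP minus EA and 3 to 30 in R minus L. It was 105 to 157 in the P slope, 3 to 8 in the A slope, 40 to 2212 between E6.5 and earlier stages and 281 to 450 between E7.5 and E6.5. Without E6.5 embryos 1 to 4 and E7.5 embryo 3, the counts were 2 in P minus A at E6.5, 556 at E7.5, 46 in its change, 6 in the P slope, 0 in the A slope, 0 between E6.5 and earlier stages and 30 between E7.5 and E6.5. Without E6.5 embryos 5 and 6 they were 15 in P minus A at E6.5, 249 in its change, 93 in the P slope and 202 between E6.5 and earlier stages.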

Other observations

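Genes of the node, the organiser at the tip of the primitive streak, were chosen for this part after their values were seen, and no test was made. Noto, a homeobox gene of the node, stood at 13.4, 34.0 and 18.5 FPKM in P sections 1, 2 and 3 of E7.0 embryo 1 and at 177 and 38.2 in P sections 1 and 2 of E7.0 embryo 2, and at 0 from P section 7 of embryo 1 and P section 3 of embryo 2 to the proximal end. Foxj1, which drives motile cilia, stood beside it at 9.74, 17.6 and 8.67 FPKM and at 109 and 55.8, and the BMP antagonist Chrd at 21.6, 50.7 and 13.1 FPKM and at 176 and 77.0. The A library of section 1 of E7.0 embryo 2 held 147 FPKM of Noto and 113 of Foxj1.

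At E7.5 the libraries with the highest Noto lay in A section 1 of embryo 1 (674 FPKM), embryo 2 (183) and embryo 3 (107), and in P section 1 of embryo 4 (69.4) and embryo 5 (34.3), where A had no library in section 1. In P section 1 of embryo 6 Noto stood at 0.927 FPKM and T at 709, in a library with 71.9% of its FPKM sum from the small RNA gene Scarna3b. The EA/EP library of the same section held 9.16 FPKM of Noto, 17.5 of Chrd, 4.35 of Foxj1 and 270 of T. Shh, a signal of the node and notochord, stood at 24.1, 9.28 and 2.13 FPKM in those A libraries of embryos 1, 2 and 3.

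In the P side of E6.5 embryo 4, Mixl1 stood at 128 FPKM in section 4, 1.47 in section 5 and 211 in section 6, and T at 20.7, 0.467 and 78.9, while Pou3f1 stood at 7.61, 20.4 and 6.57. The A library of the same section 5 had 1.09 FPKM of Mixl1 and 16.9 of Pou3f1.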
